A study of Arabidopsis thaliana with 12 samples.

How the data were processed

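Polyadenylated RNA was measured in seedlings and inflorescences of Arabidopsis thaliana, in the wild type Col-0 and in the mutant hot3-2. Per the labels' protocols, plants grew at 22 °C with 16 h of light and 8 h of dark, RNA was extracted with TRI reagent, poly(A) RNA was isolated on magnetic beads, and libraries made with a directional kit were sequenced as read pairs of 150 nt. There were 12 libraries, 3 for each genotype in each tissue. The labels do not say whether the 3 libraries of a group came from separate plants or harvests, so the p-values measure the spread between these samples, which may be technical.

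The deposited values are counts per gene, with no normalization, beside the exonic length of each gene model. Per the submitters' processing notes, reads were handled with cutadapt 4.1, STAR and featureCounts 2.0.3. The genome build, the annotation, the strand setting of the counting and the rule that chose the listed genes are not given in the sources used here. Each library listed the same 22455 genes. The total count per library ranged from 15164262 to 26011990. Gene names and products were taken from the RefSeq annotation of the assembly TAIR10.1, to which 22355 of the listed genes matched by locus identifier. The other 100 were organelle genes. The assembly was used only for names, gene models and gene neighbourhood, and no coordinates are given. In 13 pairs of genes with at least 200 counts in total, both genes had identical counts in every library, and all 13 pairs overlap on opposite strands. Counting by strand would not give both genes of such a pair equal counts, so these pairs argue against it. The strand setting itself is not given, and counts of overlapping genes, and of near-identical family members, are uncertain.

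Counts were normalized with TMM factors and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test, in a single model of all 12 libraries with 4 groups, after low-count genes were left out with filterByExpr, which kept 22032 genes. The model gave the difference between hot3-2 and wild type in seedlings, the same difference in inflorescences, and the difference between these differences. P-values were adjusted by Benjamini and Hochberg's method over the genes tested, and a gene was called at an adjusted p under 0.05. All fold changes below come from this model, hot3-2 over wild type on the log2 scale. All adjusted p-values of single genes come from this test. The SE beside a fold change is its absolute value divided by the square root of the F statistic. This SE is approximate, and can be too small for large folds where a group has few counts. CPM values use the TMM factors and are given as mean ± SD of 3 libraries. Where all libraries of a group had 0 counts, the fold is a bound computed against a floor of 3 counts over the group, and where a group had 1 to 3 counts the ratio is given with its 95% counting interval. Bounds and intervals cover counting error only.

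Before the data were examined, the comparisons, the tests, 29 gene lists with 590 members and the rule for named genes were fixed. 12 list members are not analysed here. The result of 1 further gene is not reported. The lists were the eIF5B family, light-harvesting complex, photosystem and electron transport, Calvin cycle, chlorophyll biosynthesis, plastid transcription, plastid ribosomal proteins, greening regulators, cytosolic ribosomal proteins, ribosome biogenesis, translation initiation factors, heat shock response, unfolded protein response, anthocyanin and flavonoid synthesis, salicylic acid defence, jasmonate response, glucosinolate synthesis, abscisic acid and cold response, flowering time, floral organ identity, tapetum and pollen wall, mature pollen, cell division and meristem, circadian clock, RNA silencing, senescence, root markers, seed storage and iron deficiency. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, with adjustment over the 29 lists, and again with the correlation estimated from the data. A list was described where its camera adjusted p was under 0.05 or at least 20% of its tested members were called, and is otherwise given as counts. Of all genes tested 52.5% were called in seedlings and 44.7% in inflorescences. A described list can therefore hold a smaller share of called members than all genes do.

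Named genes were chosen by a fixed rule. For each genotype comparison they were, among called genes with a mean of at least 5 CPM in that tissue and no overlap between the 3 mutant and the 3 wild-type libraries, the 10 largest rises and the 10 largest falls, plus the 5 largest of each that carry a symbol of their own. For the tissue difference they were the 5 largest called differences in each direction with a mean of at least 5 CPM over all libraries. From each list up to 3 called members with the smallest adjusted p and the member with the highest mean CPM were named, and the eIF5B family was always named. Other genes named below were chosen after their values were seen. With 3 libraries against 3, chance alone leaves 10% of genes without overlap between the groups.

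The alternatives tried were DESeq2 1.42.0, limma-voom, RLE normalization, library size alone, other count filters, models of a single tissue, organelle genes left out, the replicate number as a block, each library left out in turn, camera with an estimated correlation and fry. A stricter threshold, an adjusted p under 0.01, was also tried. Alternatives chosen after seeing the data were leaving out the locus AT3G06365 and using the log2 of its percent of counts as a covariate. Leaving out the wild-type seedling library with the highest percent there was planned as 1 of the libraries left out in turn, and only its use for this question was chosen after seeing the data. Replicate numbers differ between the labels for hot3-2: the descriptions number these libraries 1 to 3 and the titles 2 to 4. The descriptions' numbers are used here.

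The procedure was tested on simulated data drawn from the means and library sizes of the real ones, with 200 genes changed by known folds. In seedlings it recovered 67.1% of genes changed 1.5-fold, 82.4% of those changed 2-fold and 96.4% of those changed 4-fold among 21863 genes, and called 13 unchanged genes. In inflorescences it recovered 78.6%, 94.3% and 93.5% at these folds among 21858 genes and called 5 unchanged genes. For the tissue difference it recovered 35.4%, 85.7% and 87.5% among 21868 genes and called 8 unchanged genes. In the simulated seedlings a list of 30 genes shifted by 0.5 on the log2 scale was found by camera, and 0 of 28 unchanged lists were called. The simulated genes were drawn independently, whereas the estimated correlation among the real cytosolic ribosomal protein genes was 0.63. Far fewer genes were changed than the 11575 called in the real seedlings. The simulation therefore does not test false calls of correlated lists, or the normalization when many genes change.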

Results

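The libraries profiled transcript abundance in hot3-2, a mutant of HOT3, which encodes the translation initiation factor eIF5B1, a GTPase that helps the ribosomal subunits to join at the start codon. The study's title links HOT3 to the translation of nuclear photosynthesis genes and to chloroplast biogenesis. These RNA-seq libraries measured transcript levels, not translation. Seedlings and inflorescences of wild type and hot3-2 were each measured in 3 libraries. Total counts ran from 15164262 to 20662976 in seedlings and from 16974757 to 26011990 in inflorescences. Replicate libraries of a group differed by more than sampling noise, and the lowest Spearman correlation across genes between replicates was 0.984. Chi-square per degree of freedom between replicates ran from 7.65 to 61.7 in seedlings and from 2.11 to 3.36 in inflorescences. The model of all 12 libraries shares the spread of each gene across both tissues.

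HOT3 (AT1G76810) transcript was lower in the mutant in both tissues, in 6 of 6 mutant libraries. It fell from 251 ± 17.2 to 99.7 ± 8.8 CPM in seedlings (log2 fold change -1.33 ± 0.08, adjusted p = 8.96e-12) and from 204 ± 15 to 136 ± 0.884 CPM in inflorescences (-0.59 ± 0.07, adjusted p = 1.84e-06). The drop was smaller in inflorescences, with a difference between tissues of 0.74 ± 0.11 (adjusted p = 9.07e-06). The related eIF5B genes did not all move as HOT3 did. AT1G21160 rose by 1.1 ± 0.09 in seedlings, from 37.2 ± 5.18 to 79.5 ± 5.58 CPM, and by 1.05 ± 0.08 in inflorescences. AT1G76820 rose by 0.54 ± 0.15 and 0.60 ± 0.12. AT1G76720 was lower in seedlings (-0.57 ± 0.15, adjusted p = 0.00402) and higher in inflorescences (0.36 ± 0.11, adjusted p = 0.013). Its inflorescence call was lost without wild-type replicate 1 (adjusted p = 0.0619) or replicate 3 (0.0543). Its seedling call was lost with the log2 percent at AT3G06365 as a covariate (adjusted p = 0.0813). As a list, the family of 4 had 2 members higher and 2 lower in seedlings (camera adjusted p = 0.873) and 3 higher and 1 lower in inflorescences (0.278).

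**Figure D1:**
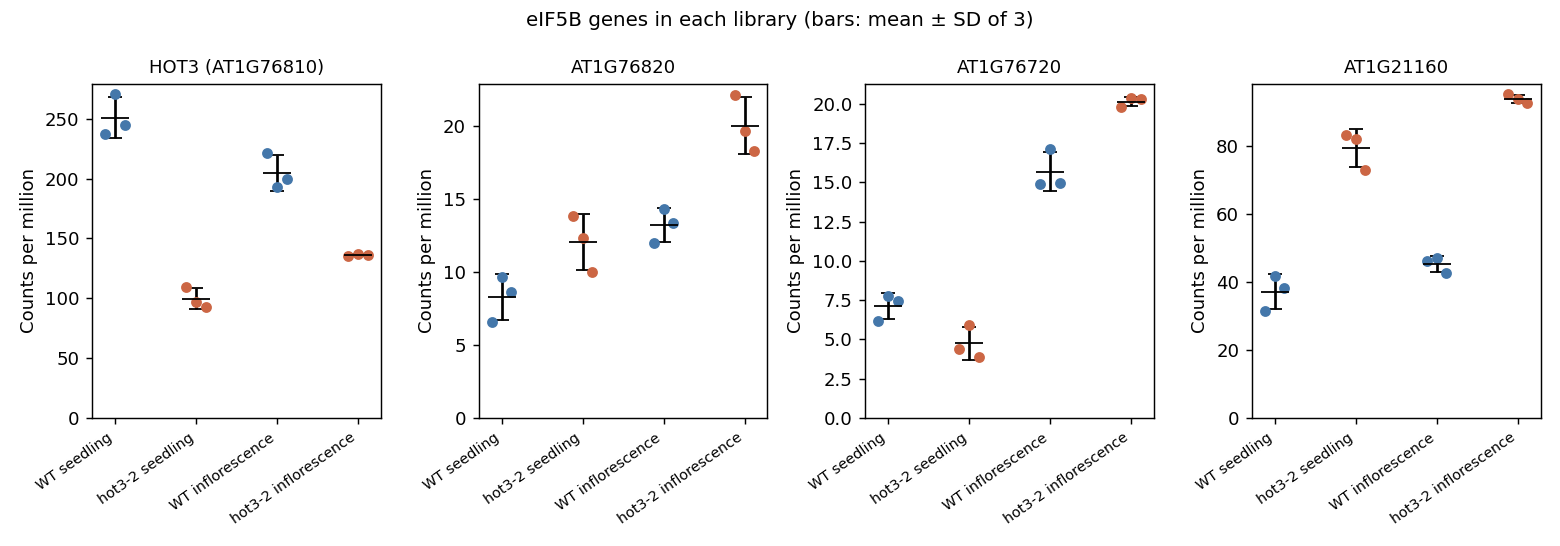
CPM of HOT3 and the 3 related eIF5B genes in each of the 12 libraries (points), with the mean ± SD of each group of 3 (bars) and a separate vertical axis per gene starting at 0. HOT3 lies lower in hot3-2 in both tissues and AT1G21160 higher in both.

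In seedlings, nuclear genes of the photosynthetic light reactions had lower transcript levels in hot3-2. Of the 21 light-harvesting complex genes, which encode antenna proteins, 19 fell and 1 rose, with a median log2 fold change of -0.82. LHCB1.4 fell from 2667 ± 147 to 957 ± 68 CPM (-1.48 ± 0.07), as did LHCA1 (-1.11 ± 0.06) and LHCB1.3, the most abundant of them (-0.82 ± 0.08). LHCB1.5 fell by 1.46 ± 0.07, but its counts equal those of an overlapping gene on the other strand and are uncertain. The camera adjusted p of the list was 3.55e-09, and the call was lost at an adjusted p = 0.188 with an estimated correlation. Of 36 photosystem and electron transport genes 31 fell and 1 rose (median -0.66, camera adjusted p = 4.74e-11, adjusted p = 0.17 with an estimated correlation). Among them the photosystem I subunit gene PSAG (-1.05 ± 0.06), the ferredoxin-NADP reductase gene FNR2 (-0.76 ± 0.06) and the cytochrome b6f gene PETC (-0.69 ± 0.06) fell. The nuclear genes of plastid ribosomal proteins also fell, 28 of 31 with none higher (median -0.37, or -0.20 with library size alone, camera adjusted p = 1.81e-08, adjusted p = 0.243 with an estimated correlation), with PRPS13 lower (-0.98 ± 0.08) and PRPS9 likewise (-0.77 ± 0.07).

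Other chloroplast lists were not called in seedlings. In the Calvin cycle 10 of 18 genes fell and 4 rose (median -0.20, or -0.03 with library size alone, camera adjusted p = 0.144). RPE (-0.85 ± 0.06) and the Rubisco small subunit gene RBCS3B (-0.67 ± 0.06) fell, whereas the abundant RBCS1A stood at -0.05 ± 0.06. In chlorophyll biosynthesis 10 of 22 genes fell and 2 rose (median -0.08, of opposite sign with library size alone, 0.0733), with CHLM lower (-1.01 ± 0.07) and PORA likewise (-2.45 ± 0.19). In plastid transcription 10 of 20 rose and 4 fell (median 0.17, or 0.35 with library size alone, 0.0526), led by the organelle RNA polymerase gene RPOTMP, which rose by 1.26 ± 0.12. Of 6 greening regulators 3 rose and none fell (median 0.35, or 0.53 with library size alone, 0.205). They included GLK1 and GNC, transcription factors that promote chloroplast development, higher by 1.17 ± 0.09 and 1 ± 0.11. Among the genes of the plastid genome, 60 of 68 fell and none rose, with a median of -1.57. Poly(A) selection retains such RNA only in part. The locus AT3G06365, which lies just downstream of a 5.8S rRNA gene, took 2.571%, 12.185% and 3.247% of counts in the wild-type seedling libraries and 2.653%, 1.71% and 0.206% in the mutant ones. Plastid genes took 1.575%, 2.334% and 1.574% in wild type and 0.762%, 0.825% and 0.763% in the mutant. Without the wild-type library with 12.185%, 52 plastid genes were lower, with a median of -1.24. Of 17 genes of the mitochondrial genome 8 fell and none rose in seedlings (median -1.16), and their percent of counts was highest, 0.0137%, in that same wild-type library.

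**Figure D2:**
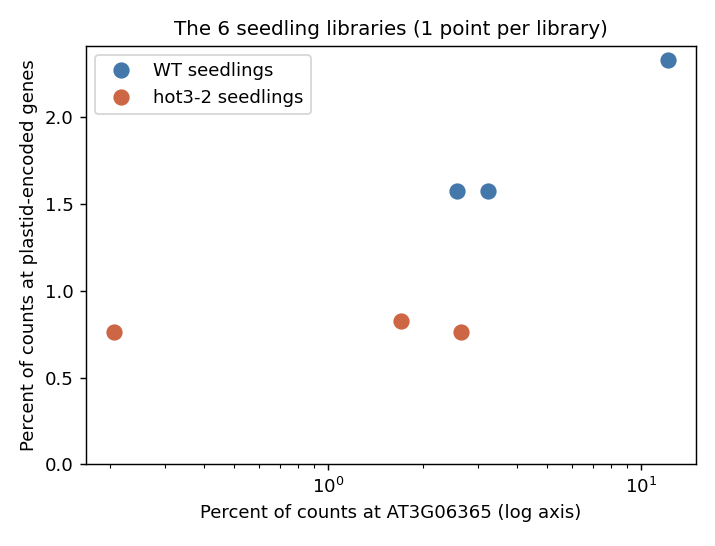
Percent of counts at plastid-encoded genes (vertical axis) against percent of counts at AT3G06365 (horizontal log axis) in the 6 seedling libraries, 1 point per library. The 3 hot3-2 libraries lie at 0.762% to 0.825% of plastid counts and the 3 wild-type libraries at 1.574% to 2.334%.

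Genes of the cytosolic translation machinery had higher transcript levels in hot3-2 seedlings. All 106 cytosolic ribosomal protein genes rose, with a median of 1.07. RPL4D rose from 263 ± 5.95 to 717 ± 26.3 CPM (1.45 ± 0.06), RPL30B by 1.51 ± 0.06 and the abundant RPL3A by 0.92 ± 0.06. The camera adjusted p was 1.54e-37, and the call was lost at an adjusted p = 0.164 with an estimated correlation. Of 31 ribosome biogenesis genes 29 rose and 1 fell (median 1.2, camera adjusted p = 2.72e-19, adjusted p = 0.000163 with an estimated correlation). The nucleolar protein genes NOP56 and FIB2 rose by 2.22 ± 0.06 and 2.54 ± 0.07, NOP56 from 72.3 ± 1.03 to 336 ± 14 CPM. Of 33 translation initiation factor genes other than eIF5B, 24 rose and 3 fell (median 0.66, camera adjusted p = 6.95e-08). The eIF5 gene AT1G36730 rose by 1.14 ± 0.06 and eIF3A by 1.21 ± 0.08, whereas eIF4A1 stood at 0.10 ± 0.06. Of 21 genes of cell division and the meristem 13 rose and 1 fell (median 0.41, camera adjusted p = 0.000365). TSO2, a ribonucleotide reductase subunit, rose by 1.65 ± 0.08 and PCNA1 by 1.16 ± 0.10, and the receptor kinase gene CLV1 fell by 0.83 ± 0.07.

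Hormone, defence and pigment genes changed in seedlings in both directions. Of 16 jasmonate response genes 14 fell and 2 rose (median -1.61, camera adjusted p = 8.07e-08). The jasmonate synthesis gene OPR3 fell from 215 ± 26.2 to 44.2 ± 6.58 CPM (-2.28 ± 0.10), and the repressor genes JAZ10 (-2.41 ± 0.11) and JAZ5 (-2.79 ± 0.13) fell. Of 17 salicylic acid defence genes 10 fell and 1 rose (median -0.52, or -0.34 with library size alone, camera adjusted p = 0.0312, adjusted p = 0.106 with an estimated correlation). The 1 that rose was PR5 (2.28 ± 0.11), and EDS1 (-0.63 ± 0.07) and WRKY70 (-0.64 ± 0.08) fell. Of 14 anthocyanin and flavonoid genes 13 rose and none fell (median 1.70, camera adjusted p = 4.59e-09), with the pigment synthesis genes LDOX and DFR higher by 3.71 ± 0.18 and 3.38 ± 0.15. Of 20 heat shock genes 12 fell and 2 rose (median -0.49, or -0.31 with library size alone, camera adjusted p = 0.0155, adjusted p = 0.247 with an estimated correlation), with HSFA2 lower (-2.87 ± 0.23) and HSP90.1 likewise (-1.55 ± 0.13). Among clock genes 8 of 13 fell and none rose (median -0.55, camera adjusted p = 0.00122). PRR5 (-1.31 ± 0.09) and TOC1 (-0.62 ± 0.06) fell.

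Markers of other organs and stages also differed. All 10 seed storage genes were higher in hot3-2 seedlings (median 7.49, or 6.29 with genes at 0 counts in wild type set to their bound, camera adjusted p = 1.95e-09). The cruciferin gene CRA1 rose from 0.508 ± 0.345 to 46.1 ± 7.57 CPM. The labels give no seedling age, and these libraries do not separate remaining seed material or ungerminated seeds from slower development. Of 14 root markers 8 rose and 1 fell (median 0.68, camera adjusted p = 0.0587), and PYK10, a root and endoplasmic reticulum body beta-glucosidase, rose by 0.61 ± 0.07. These shifts accompanied the lower light-harvesting, photosystem and plastid-encoded transcripts and the higher ribosomal protein transcripts in the same libraries. Of 7 iron deficiency genes 5 rose and 1 fell (median 1.45, 0.073), with the iron transporter gene IRT1 higher by 1.45 ± 0.11 and the ferritin gene FER1 lower (-0.67 ± 0.07). In abscisic acid and cold response 9 of 20 genes rose and 4 fell (median 0.20, or 0.37 with library size alone, 0.0696), with COR15A up by 3.10 ± 0.12. In the unfolded protein response 8 of 16 rose and 3 fell (median 0.12, or 0.30 with library size alone, mean -0.01, 0.467), with CRT1B higher by 0.67 ± 0.07 and BIP3 lower (-1.80 ± 0.25). Senescence genes split 4 higher and 4 lower of 11 (median -0.15, of opposite sign with library size alone, 0.467), with ASN1 lower (-4.1 ± 0.08). Glucosinolate genes split 2 higher and 4 lower of 10 (median -0.08, of opposite sign with library size alone, 0.46), with CYP79B3 lower (-1.09 ± 0.09). RNA silencing genes split 2 and 2 of 11 (median 0.03, 0.21 with library size alone and of opposite sign with RLE factors, 0.873), with AGO2 higher by 0.58 ± 0.11.

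Reproductive lists were near background or mixed in seedlings. Of 10 flowering time genes 1 rose and 3 fell (median -0.07, of opposite sign with library size alone and -0.10 with RLE factors, camera adjusted p = 0.723). The floral promoter SOC1 fell by 1.38 ± 0.11 and the floral repressor FLC rose by 0.96 ± 0.26. Floral organ identity genes split 2 higher and 3 lower of 16 (median 0.06, or 0.21 with library size alone, mean -0.08 and test downward, 0.873), with SEP4 lower (-1.43 ± 0.14). Tapetum and pollen wall genes split 2 higher and 1 lower of 15 (median 0, mean -0.27 and test upward, 0.873), with GRP19 at 0.136 ± 0.0991 and 1.09 ± 0.166 CPM. Among 9 mature pollen genes 1 was higher (median -0.07, of opposite sign with library size alone, mean 0.07 and test upward, 0.873).

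Seed storage genes were 5 of the 10 largest rises in seedlings. SESA3, SESA2, SESA5 and SESA1, genes of 2S albumin storage proteins, had 0 counts in the wild-type libraries and were at least 504-, 283-, 270- and 216-fold higher in hot3-2. CRU3 rose by 8.43 ± 0.35. Against 1 to 3 counts in wild type, the ratio was 460 for AT2G18190 (95% counting interval 157 to 2232), 349 for AT2G05915 (119 to 1695), 360 for EPR1 (99.5 to 2981), 260 for AT1G64795 (71.7 to 2152) and 222 for the defensin-like gene LCR67 (75.6 to 1078). The largest falls were in the defensin genes PDF1.2 (-5.24 ± 0.25) and PDF1.2c (-5.02 ± 0.27), the thionin gene AT1G66100 (-4.78 ± 0.14), PCR1 (-4.64 ± 0.23), the tyrosine aminotransferase gene TAT3 (-4.56 ± 0.19), AT1G76640, CYP71B29, the asparagine synthetase gene ASN1, AT3G22235 and XTH25. ASN1 was by far the most abundant of these, falling from 1092 ± 123 to 63.8 ± 3.68 CPM. PDF1.2 and PDF1.2c are close copies that can share reads.

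In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 11575 of 22032 genes between hot3-2 and wild-type seedlings, 5755 higher and 5820 lower, of which 2779 changed at least 2-fold (1636 higher and 1143 lower). Camera called 13 of 29 lists, 7 of them also with an estimated correlation. Adjusted over the list alone, the counts were 32 lower for photosystem, 3 higher for chlorophyll biosynthesis, 14 higher for cell division, 1 higher for the clock, 1 higher and 0 lower for tapetum and 0 for mature pollen, and unchanged for the other lists. With library size alone in place of TMM factors the median of all genes moved from 0 to 0.16 and 68.5% of calls were higher instead of 49.7%. The plastid ribosomal protein genes called lower then numbered 16.

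**Figure D3:**
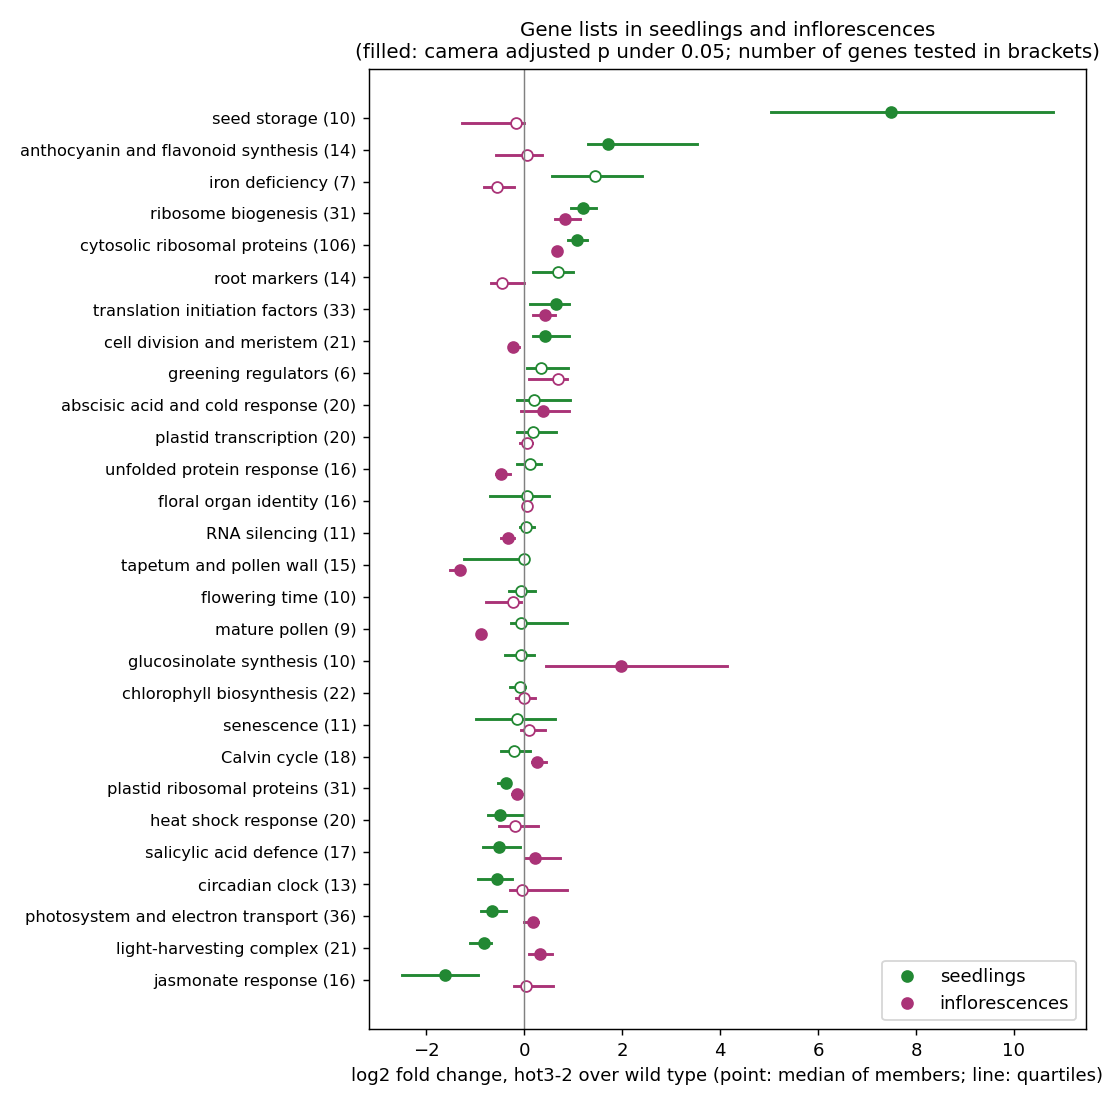
Median log2 fold change (points) and quartiles (lines) of the members of 28 gene lists in seedlings and inflorescences, hot3-2 over wild type, ordered by the seedling median. Filled points have a camera adjusted p under 0.05, and light-harvesting genes lie at -0.82 in seedlings and 0.32 in inflorescences.

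In inflorescences the same translation lists were higher in hot3-2. All 106 cytosolic ribosomal protein genes rose (median 0.67, camera adjusted p = 1.98e-42, adjusted p = 0.124 with an estimated correlation), with RPS2A up by 1.06 ± 0.07 and RPL4A by 0.92 ± 0.06. Of 31 ribosome biogenesis genes 29 rose and none fell (median 0.84, camera adjusted p = 5.58e-24). FIB2 rose by 1.4 ± 0.07 and NOP56 by 1.15 ± 0.06, from 203 ± 3.53 to 451 ± 7.6 CPM. Of 33 initiation factor genes 26 rose and 3 fell (median 0.42, camera adjusted p = 5.89e-10), with the eIF5 gene AT1G36730 up by 1.28 ± 0.06 and eIF3A by 0.87 ± 0.07.

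Photosynthesis genes were higher rather than lower in inflorescences, by smaller amounts. Of 21 light-harvesting genes 14 rose and 1 fell (median 0.32, camera adjusted p = 4.82e-05, adjusted p = 0.39 with an estimated correlation), with LHCB1.1 up from 474 ± 21.5 to 1546 ± 38.2 CPM (1.71 ± 0.09) and LHCB2.1 up by 1.2 ± 0.08. Of 36 photosystem genes 17 rose and 2 fell (median 0.17, or 0.11 with library size alone, camera adjusted p = 0.00087, adjusted p = 0.506 with an estimated correlation), with FD2 up by 0.44 ± 0.06 and PSAD1 by 0.40 ± 0.06. Of 18 Calvin cycle genes 13 rose and 1 fell (median 0.25, camera adjusted p = 6.4e-05, adjusted p = 0.124 with an estimated correlation), with the Rubisco activase gene RCA up by 0.85 ± 0.07. Plastid ribosomal protein genes were lower here too, 14 of 31 with none higher (median -0.16, camera adjusted p = 0.00476, adjusted p = 0.576 with an estimated correlation), with PRPL12A lower (-0.42 ± 0.06). GLK1 rose by 1.51 ± 0.10 and GNC by 0.88 ± 0.12, in a list of 6 greening regulators with 4 higher and 1 lower (median 0.69, 0.0702). Chlorophyll biosynthesis genes split 7 higher and 5 lower of 22 (median -0.005, -0.07 with library size alone and of opposite sign with RLE factors, mean 0.02 and test upward, 0.549), with GUN4 higher by 0.78 ± 0.08 and DVR lower (-0.75 ± 0.07). Plastid transcription genes split 5 and 2 of 20 (median 0.06, of opposite sign with library size alone, 0.371), with SIG1 higher by 0.57 ± 0.08. Of 68 genes of the plastid genome 2 rose and 2 fell, and of 17 of the mitochondrial genome 3 fell and none rose (median -0.34).

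Clock genes in inflorescences went both ways, 5 of 13 higher and 4 lower (median -0.05, or -0.11 with library size alone, mean 0.21 and camera adjusted p = 0.999). The morning genes CCA1, PRR9, RVE8 and RVE1 rose by 1.44 ± 0.17, 1.34 ± 0.24, 1.25 ± 0.23 and 0.87 ± 0.14. Among the 5 evening genes TOC1, LUX, ELF4, GI and BOA, BOA (-0.97 ± 0.08) and TOC1 (-0.31 ± 0.06) fell. The others lay at or above the median of these evening genes, -0.22. These clock gene changes stood beside the higher light-harvesting and Calvin cycle transcripts in the same libraries.

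Genes of anthers and pollen were lower in hot3-2 inflorescences. Of 15 tapetum and pollen wall genes 14 fell and none rose (median -1.31, camera adjusted p = 3.71e-07). The pollen coat gene GRP17 fell from 1318 ± 44.4 to 552 ± 19.7 CPM (-1.26 ± 0.10), and A6 (-1.62 ± 0.08) and LAP5 (-1.45 ± 0.10) fell. All 9 mature pollen genes fell (median -0.88, camera adjusted p = 0.00699, adjusted p = 0.0768 with an estimated correlation), with VGD1 lower (-0.94 ± 0.07). Floral organ identity genes did not follow: 1 of 16, SEP3 (0.35 ± 0.07), was called (median 0.04, of opposite sign with library size alone, 0.549). Of 16 unfolded protein response genes, which serve protein folding in secretory cells, 12 fell and 1 rose (median -0.49, camera adjusted p = 4.82e-05, adjusted p = 0.162 with an estimated correlation), with ERDJ3A lower (-1.73 ± 0.14). These lower marker levels accompanied every group described for these libraries.

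Glucosinolate synthesis was the most strongly raised list in inflorescences, with 9 of 10 genes higher and none lower (median 1.98, camera adjusted p = 9.8e-11). CYP79F1 rose from 0.643 ± 0.0875 to 28.6 ± 1.93 CPM (5.46 ± 0.16), BCAT4 by 5.19 ± 0.15 and MAM1 by 3.75 ± 0.09, all of them genes of methionine-derived glucosinolates. Of 17 salicylic acid defence genes 8 rose and 1 fell (median 0.22, camera adjusted p = 0.00476, adjusted p = 0.0599 with an estimated correlation), with CBP60G up by 1.66 ± 0.15 and WRKY70 by 1.14 ± 0.07. Of 20 abscisic acid and cold genes 11 rose and 3 fell (median 0.39, camera adjusted p = 0.00087, adjusted p = 0.08 with an estimated correlation), with RD29A up by 1.2 ± 0.06 and RAB18 by 1.28 ± 0.10. Of 11 RNA silencing genes 7 fell and none rose (median -0.33, camera adjusted p = 0.00581, adjusted p = 0.489 with an estimated correlation), with RDR6 lower (-0.86 ± 0.11). Of 21 cell division and meristem genes 11 fell and 1 rose (median -0.23, camera adjusted p = 0.0466, adjusted p = 0.124 with an estimated correlation), with the stem cell gene WUS lower (-0.76 ± 0.15).

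The remaining lists were not called in inflorescences. Jasmonate response genes split 3 higher and 2 lower of 16 (median 0.04, of opposite sign with library size alone, camera adjusted p = 0.411), with JAZ7 up by 1.67 ± 0.09. Anthocyanin and flavonoid genes split 6 and 4 of 14 (median 0.05, of opposite sign with library size alone, mean -0.04 and test upward, 0.667), with DFR lower (-1.2 ± 0.13). Heat shock genes split 5 and 6 of 20 (median -0.20, mean 0.06 and test downward, 0.667), with HSP18.2 higher by 1.2 ± 0.19. Of 10 flowering time genes 5 fell and none rose (median -0.23, 0.221), with FT lower (-1.4 ± 0.13). Senescence genes split 4 and 2 of 11 (median 0.10, or 0.04 with library size alone, 0.549), with SAG13 higher by 0.97 ± 0.10. Root markers split 1 and 3 of 14 (median -0.45, 0.549), with COBL9 lower (-1.1 ± 0.31). Of 7 iron deficiency genes 2 fell and none rose (median -0.56, 0.296), with FER1 lower (-0.24 ± 0.07). Of 10 seed storage genes 1, OLEO1, was lower, at 0.353 ± 0.0733 and 0.0951 ± 0.0428 CPM (median -0.16, 0.667).

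The largest rises in inflorescences included several genes that also rose strongly in seedlings. AT2G04050, a MATE efflux family gene, rose by 6.65 ± 0.20 in inflorescences and 4.25 ± 0.12 in seedlings, and the transcription factor gene NAC044 by 5.85 ± 0.20 and 6.51 ± 0.20. NAC044 reached 41 ± 3.25 CPM in hot3-2 inflorescences against 0.655 ± 0.412 CPM in wild type. AT2G35570 rose by 6.52 ± 0.19, AT1G64795 by 6.08 ± 0.24, AT4G08093 by 5.81 ± 0.20, AT4G05380 by 5.29 ± 0.16 and the overlapping pair AT2G05914 and AT2G05915 by 4.85 ± 0.14 and 4.37 ± 0.16. The isopropylmalate isomerase gene IPMI2, of the same glucosinolate pathway, rose by 4.34 ± 0.19. The largest falls were at 1 locus where AT1G07887 (-2.78 ± 0.13), MRD1 (-2.76 ± 0.13) and the crossover gene HEI10 (-2.45 ± 0.12) overlap, so that their counts cannot be assigned with certainty. AT1G04660, the sugar transporter gene STP2 (-2.23 ± 0.17), AT1G78450, AT5G62080, AT1G75870, AT5G52160 and AT2G28680 followed, with log2 fold changes between -2.31 and -2.07. BAS (-1.99 ± 0.11) and RHS14 (-1.87 ± 0.18) fell.

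In all, 9848 of 22032 genes were called between hot3-2 and wild-type inflorescences by edgeR's quasi-likelihood test, 4206 higher and 5642 lower, of which 1933 changed at least 2-fold (777 higher and 1156 lower). The balance of directions depends on the model: 42.7% of calls were higher here, 33.7% with library size alone, and 51.2% in a model of the 6 inflorescence libraries, with 6257 higher and 5961 lower. Camera called 15 of 29 lists, 4 of them also with an estimated correlation. Adjusted over the list alone, the counts were 2 lower for light-harvesting, 18 higher for photosystem, 14 higher for the Calvin cycle, 2 and 1 for plastid transcription, 4 lower for initiation factors, 15 lower for tapetum, 12 and 4 for abscisic acid and cold, 5 lower for the clock and 8 lower for RNA silencing, and unchanged for the other lists. The 17 photosystem genes called higher became 10 without wild-type replicate 2 or 3 and 11 without hot3-2 replicate 1 or 2, the 13 Calvin cycle genes became 8 without hot3-2 replicate 2, and the 11 cell division genes called lower became 6 without wild-type replicate 2 or 3, 7 without hot3-2 replicate 1 and 5 without hot3-2 replicate 3. The camera call of cell division was lost without each of the 3 wild-type replicates and without hot3-2 replicate 1 (adjusted p from 0.0509 to 0.0807).

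Fold changes in the 2 tissues were only weakly related. Across 22032 genes, which are not independent replicates, Pearson's r was 0.197 and Spearman's rho 0.189. Of 5856 genes called in both tissues 4053 changed in the same direction. There were 2136 genes higher in both against 1099 for independent lists of these sizes (odds ratio 4.05), and 1917 lower in both against 1490 (odds ratio 1.65, Fisher's exact test, two-sided, p = 8.94e-49). The other 743 and 1060 were higher in seedlings and lower in inflorescences, and the reverse.

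The test of the difference between tissues called 8686 genes, 3990 with a more positive and 4696 with a more negative effect in inflorescences, of which 2887 differed at least 2-fold. The light-harvesting genes differed most evenly, with 20 of 21 more positive in inflorescences (median difference 1.34, camera adjusted p = 1.04e-14, adjusted p = 0.073 with an estimated correlation). The 106 ribosomal protein genes rose less in inflorescences, by a median of -0.42, or -0.66 with library size alone, and 63 of them differed (camera adjusted p = 5.05e-10, adjusted p = 0.383 with an estimated correlation). Jasmonate genes were more positive in inflorescences in 13 of 16 cases (median 1.82, camera adjusted p = 1.16e-10) and glucosinolate genes in 9 of 10 (median 2.1, 4.62e-10). Anthocyanin genes were more negative in 13 of 14 (median -1.44, camera adjusted p = 4.95e-08). Adjusted over the list alone these counts were 20, 69, 15, 9 and 13. Among single genes PCR1 differed by 8.5 ± 0.40 and CYP79F1 by 5.47 ± 0.19. Camera called 22 lists, 9 of them also with an estimated correlation. The 7 lists not called were the eIF5B family (adjusted p = 0.115), translation initiation factors (0.115), plastid transcription (0.275), floral organ identity (0.454), flowering time (0.589), abscisic acid and cold response (0.719) and greening regulators (0.729). Which direction was in the majority depends on the scaling and on a single library: 4399 were positive and 4111 negative with RLE factors, 4483 and 4192 with DESeq2, and 4661 and 3321 without wild-type seedling replicate 2. With library size alone 23.8% of the called differences were positive instead of 45.9%, and the median of all genes moved from -0.09 to -0.33.

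**Figure D4:**
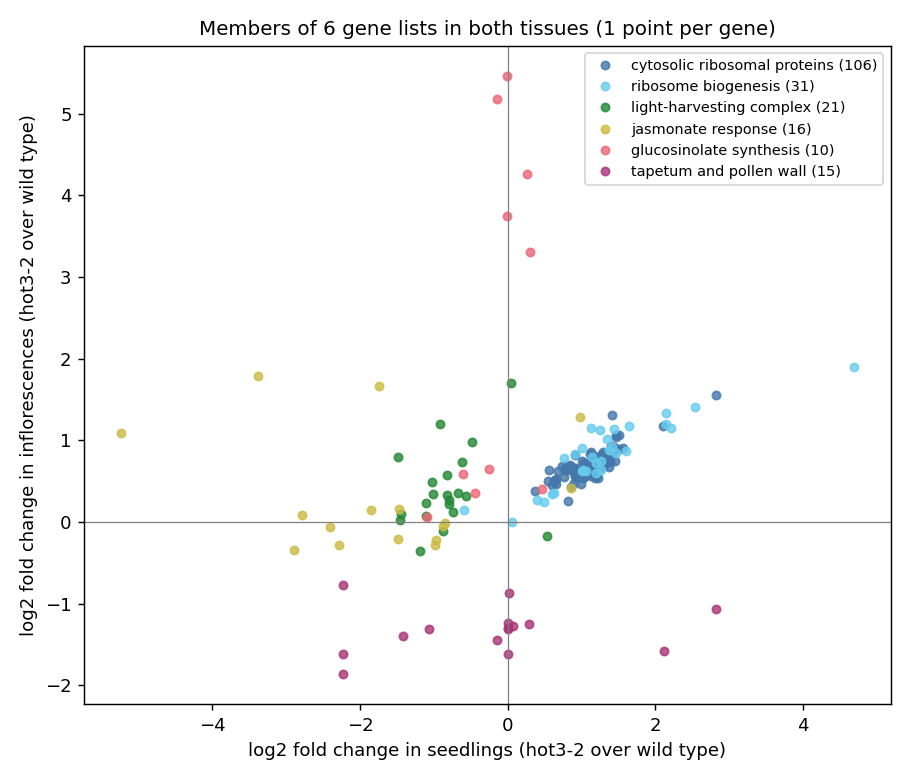
Log2 fold change of each gene in seedlings (horizontal axis) and in inflorescences (vertical axis), hot3-2 over wild type, for the members of 6 gene lists, 1 point per gene. All 106 ribosomal protein genes lie above 0 on both axes, while seedling values of tapetum genes rest on few counts.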

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

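The test of green tissue share and the test of harvest time were chosen only after the result was seen, and the test of matched genes before. The criterion that would have excluded a difference in harvest time was also made stricter after the outcome of that test was seen. The effects below differed between seedlings and inflorescences by the test of the difference itself. Other splits of the libraries bear on the counts of calls. The 6 seedling libraries can be split in 10 ways, and 1 of these, the real one, gave as many as the 11575 genes called, the highest other giving 0. The 6 inflorescence libraries also allow 10, where 1, the real one, gave 9848 and the highest other 0. With 10 splits the share can never be under 0.05. Every other split of a tissue's libraries places both genotypes in each group, so the genotype difference adds to the spread within groups. The values of 0 are therefore no measure of false calls. For the difference between tissues, 1 of the 100 combined splits, the real one with 8686 genes, was as large. The highest other gave 5565 and kept the real split in 1 tissue. These splits ask whether the genotype labels could be exchanged, and 1 in 100 is under 0.05. They do not ask whether the genotype effects differ between tissues, so no conclusion on that is drawn from them. The highest of the 81 combinations with neither real split gave 0.

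Light-harvesting and photosystem genes were lower in hot3-2 seedlings and higher in inflorescences, with median differences between tissues of 1.34 and 0.77, although with an estimated correlation the adjusted p was 0.188 and 0.17 in seedlings, 0.39 and 0.506 in inflorescences and 0.073 and 0.0728 for the difference. A lower share of green tissue in the mutant seedlings would lower Calvin cycle genes by as much, but the median of the 57 light-harvesting and photosystem genes lay -0.54 from that of the 18 Calvin cycle genes (-0.75 and -0.20, permutation p = 0.00027 with 100000 resamples over genes, which are not independent), which argues against it as the only cause. A different time of harvest stays open: 4 of 5 evening clock genes were lower (median -0.62), and the 4 morning genes had a median of -0.45 with 1 called. Remaining seed material or slower development of the mutant seedlings was not tested and stays open too. All 10 seed storage genes were higher in the same libraries (median 7.49, or 6.29 with genes at 0 counts in wild type set to their bound). In inflorescences morning genes had a median of 1.3 and evening genes -0.22, so harvest times may have differed there. The share of green tissue was not tested in inflorescences. In these libraries 14 of 15 tapetum and pollen wall genes and all 9 mature pollen genes were lower in hot3-2. The genotype itself remains an open explanation.

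Cytosolic ribosomal protein genes rose more in seedlings than in inflorescences, with a median difference of -0.42 (-0.66 with library size alone, and adjusted p = 0.383 with an estimated correlation), and ribosome biogenesis genes likewise with -0.39 (-0.62 with library size alone). Each ribosomal protein gene was set against the 10 genes closest in length, GC content and abundance. The 106 genes had a median excess of 1.03 in seedlings and 0.49 in inflorescences. For the mean excess the permutation p was 1e-04 in each tissue, the smallest that 10000 sign changes can give. The sign of each gene was changed apart, although the genes are not independent (estimated correlation 0.63). The matched genes had medians of 0.05 in seedlings and 0.17 in inflorescences, where all genes had -0.07, so a part of the rise in inflorescences is shared by genes of like length, GC content and abundance and most of it is not. A change in the share of growing cells was not tested apart from the genotype, and the estimated correlation among these genes is high enough to end the camera call in both tissues as well.

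Other lists differed between tissues as follows, given as the median difference of log2 fold changes, inflorescences minus seedlings. More positive in inflorescences were glucosinolate synthesis (2.1), jasmonate response (1.82), circadian clock (0.73), salicylic acid defence (0.66), senescence (0.54), Calvin cycle (0.50), heat shock (0.33), plastid ribosomal proteins (0.26) and chlorophyll biosynthesis (0.12, which turned to -0.12 with library size alone). More negative were seed storage (-6.50), iron deficiency (-1.61), anthocyanin and flavonoid synthesis (-1.44), tapetum and pollen wall (-1.3), root markers (-1.003), mature pollen (-0.77), cell division and meristem (-0.77), the unfolded protein response (-0.76) and RNA silencing (-0.45). With library size alone the differences shrank to 0.48 for the clock, 0.42 for salicylic acid defence, 0.29 for senescence, 0.26 for the Calvin cycle, 0.08 for heat shock and 0.02 for plastid ribosomal proteins, and that of RNA silencing grew to -0.70. The seedling values behind the tapetum and pollen lists rest on few counts, and so do the inflorescence values behind seed storage, where members such as SESA3 have 0 counts, so -6.50 is no measured size of a difference. With an estimated correlation the adjusted p rose to 0.0578 for the Calvin cycle, 0.0728 for photosystem genes, 0.14 for chlorophyll biosynthesis, 0.325 for plastid ribosomal proteins, 0.269 for heat shock and senescence, 0.224 for the unfolded protein response and iron deficiency, 0.108 for mature pollen and root markers and 0.419 for RNA silencing.

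Among single genes the adjusted p of the difference was 3.32e-14 for CYP79F1, 2.41e-12 for PCR1, 9.07e-06 for HOT3 and 0.000572 for AT1G76720. It was 8.45e-09 for AT2G18190, 0.00265 for PDF1.2, 0.000146 for SESA2, 1.78e-07 for AT1G20130, 0.00031 for AT5G62730, 0.000764 for CYP705A24, 0.00918 for CYP71B31 and 0.0105 for AAE11, which each have few or no counts in a group. Without hot3-2 inflorescence replicate 3 the value for PDF1.2 was 0.906, without wild-type seedling replicate 3 that for CYP71B31 was 0.0937, and without wild-type seedling replicate 1 that for AAE11 was 0.106.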

How the results depend on the processing

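The alternatives built on AT3G06365 were chosen only after the result was seen. Totals of called genes stayed within 1.5 times of those reported in every alternative run. Counts by direction moved further with library size alone, where lower seedling calls went from 5820 to 3709 and negative differences from 4696 to 8186, as did some list counts. Leaving out each library in turn gave 10554 to 11668 genes in seedlings, 8144 to 8456 in inflorescences and 7771 to 9437 for the tissue difference. Models of a single tissue gave 9823 in seedlings and 12218 in inflorescences, so which tissue had more calls depends on the model. HOT3 kept its direction and call in all of them. The lists called by camera fell to 7 in seedlings and 4 in inflorescences with an estimated correlation, and fry, which does not compare a list with other genes, gave 24 in seedlings and 22 in inflorescences. 2 results reversed: PTAC6 in seedlings stood at 0.0092 with library size alone against -0.17, and the clock list in inflorescences pointed down under fry (adjusted p = 0.0251) and up under camera. The shift of PTAC6 went with that of all genes, whose seedling median moved from 0 to 0.16 with library size alone. The cause of the clock reversal was not tested. Of the other values of named genes under alternatives 4662 kept their direction and side of the threshold, 86 lost the call and 10 gained it. With the replicate number as a block the calls were 10707 in seedlings, 8486 in inflorescences and 7482 for the difference by the descriptions' numbers, and 10893, 9303 and 8166 by the titles' numbers. A pairing by number was looked for in the log2 CPM of each library minus the mean of its group. Across genes, these deviations of same-numbered libraries correlated at -0.383, 0.106 and -0.083 in seedlings by the descriptions' numbers. In inflorescences they correlated at -0.080, -0.012 and -0.053. By the titles' numbers the values were 0.275 and -0.062 in seedlings and 0.039 and 0.012 in inflorescences. Deviations in a group of 3 sum to 0, which forces mixed signs, so these values cannot show or exclude a pairing. With the log2 percent at AT3G06365 as a covariate 9761 of the seedling calls were called again, and 11574 with that locus left out. Few counts limit the folds of genes at 0 to 3 counts in a group, given above as bounds or intervals.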

Other observations

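The test on plastid-encoded genes was chosen only after the result was seen, and the others before. Genes outside the fixed lists were followed up because 4 genes had caught attention in both tissues: the MATE family genes AT2G04050 and AT2G04070, the ATPase gene AT2G18193 and the glucosyltransferase gene UGT74E2. AT2G04070 rose by 6.35 ± 0.23 in seedlings and 3.46 ± 0.41 in inflorescences, AT2G18193 by 4.89 ± 0.09 and 2.88 ± 0.08, and UGT74E2 by 2.72 ± 0.08 and 2.57 ± 0.07. The gene lists below were drawn up after these genes were noticed and before their own values were looked at. GMI1, which acts in repair of broken DNA, rose by 3.72 ± 0.13 and 1.36 ± 0.10.

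A hypothesis for the first 4 genes is the response to impaired mitochondria, in which UGT74E2 and some MATE genes are known to be induced. Of 13 other genes of that response 11 were higher in seedlings and none lower (median 1.89, camera adjusted p = 1.8e-08), and 9 were higher and 1 lower in inflorescences (median 0.73, 5.14e-06). With an estimated correlation the unadjusted p was 0.00147 and 0.00524. The alternative oxidase gene AOX1A rose by 1.22 ± 0.07 and 1.78 ± 0.07, the transcription factor gene NAC013 by 2.28 ± 0.11 and 0.73 ± 0.10, and NDB4 by 3.73 ± 0.30 and 2.19 ± 0.28. The values are consistent with such a response in hot3-2, though several of these genes also answer to other stresses and the lower mitochondrial-encoded transcripts in seedlings were not separated from carry-over.

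For NAC044 and GMI1 the hypothesis was a response to DNA damage. Of 7 other genes of that response 6 were higher in seedlings (median 1.03, camera adjusted p = 0.000792), among them PARP2 (1.97 ± 0.11), BRCA1 (1.45 ± 0.12) and XRI1 (1.03 ± 0.13). In inflorescences 2 were higher, PARP2 (1.19 ± 0.10) and BRCA1 (0.43 ± 0.11), with a median of 0.31 (camera adjusted p = 0.0359, unadjusted p = 0.0771 with an estimated correlation). The seedling values are consistent with a DNA damage response, but PARP2 and BRCA1 could also rise with cell division, whose genes were higher in the same seedlings.

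Plastid-encoded transcripts were lower in hot3-2 seedlings. Carry-over of RNA without poly(A) tails, as read from the percent of counts at AT3G06365, was a candidate cause. With the log2 of that percent as a covariate, and a single slope for all 12 libraries, the median was still -1.08, against -1.57 before. Of the 60 genes 44 remained called, which argues against carry-over in that form as the only cause. The hot3-2 library with 2.653% at AT3G06365 had 0.762% of plastid counts, and the wild-type library with 2.571% had 1.575%. Carry-over that this locus does not track stays open beside the genotype, as 8 of 17 mitochondrial-encoded genes were also lower in seedlings (median -1.16).

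DNA near HOT3 that differs from wild type would leave an excess of genes changed at least 2-fold in the same direction in both tissues around it. By gene order in TAIR10.1, 2 of 499 genes within 1 Mb of HOT3 were of this kind (0.401%) against 324 of 21447 elsewhere (1.51%), a ratio of 0.265 (Fisher's exact test, two-sided, p = 0.0377), so there was no excess.

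The study's title names the Kozak motif, the sequence around the start codon. Transcript changes followed it little: the 8185 genes with a purine 3 bases before the start codon and a G just after it differed from the 1976 genes with neither by 0.07 in median log2 fold change in both tissues (0.0709 in seedlings and 0.0698 in inflorescences). This says nothing of translation, which was not measured in these libraries.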
